A study of Homo sapiens with 30 samples.

How the data were processed

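RNA was measured in 5 human cell lines grown from T-cell acute lymphoblastic leukaemia (PEER, TALL-1, MOLT-16, Loucy and PER-117). Each was treated with decitabine, a cytidine analogue that traps and depletes DNA methyltransferases, at 1 µM for 48 h, or with the vehicle dimethyl sulfoxide (DMSO). There were 3 libraries per line and treatment, 30 in all, made with a kit that sequences the 3′ ends of polyadenylated RNA on its own strand (QuantSeq 3′ mRNA-Seq FWD). According to the submitters' processing notes the reads were aligned with STAR 2.4.2a to GRCh38 (hg38) and tested with DESeq2. The deposited values are read counts per gene in 1 file per library, with columns for unstranded reads, reads on the gene's strand and reads on the opposite strand. The unit was checked on the files: all values were whole numbers, and reads on the gene's strand outnumbered those on the opposite strand 12.8 to 15.2 times in every library, so the gene-strand column was used. The annotation release used for counting is not given in the sources used here. Of 60554 gene identifiers, 56996 were matched to GENCODE 29 without their version number, which gave symbols, positions and biotypes, and 3558 had no symbol.

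Groups were taken from the sample titles. For the PEER DMSO libraries the titles and the file names exchange replicates 2 and 3, and the title was used. The labels do not say whether the 3 libraries of a group are separate cultures. The p-values therefore measure only the spread between these samples, which is possibly technical. Total counts per library on the gene's strand ran from 2.20 M to 15.4 M reads. Intervals, ratios and floors from read counts cover counting error only, since reads without molecular identifiers are not independent molecules.

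All 30 libraries were fitted together in edgeR 4.0.16 (R 4.3.3), with a mean for each of the 10 groups, TMM scaling, the filterByExpr filter with a minimum count of 10, and the quasi-likelihood F test on 20 residual degrees of freedom. The common dispersion was 0.0280. The filter left 15081 genes. Benjamini-Hochberg adjustment was made over these genes within each comparison, and a gene was called at an adjusted p under 0.05. Levels are given in CPM, counts scaled to 1 M reads on TMM-scaled library sizes, as the mean ± SD of n = 3 libraries. Fold changes are given on the log2 scale with an approximate standard error (SE). The SE is the absolute log2 change divided by the square root of its F value, and was not estimated by the fit itself. For genes with few reads in a group it is not a reliable measure of error. The comparisons were decitabine against DMSO in each line, the difference of the responses between the 5 lines (4 degrees of freedom), the genes called the same way in each line, and a fit in which the lines served as replicates. In this last fit the counts of the 3 libraries of a group were summed and the lines were the 5 pairs. DMSO libraries of the 5 lines were also compared with each other.

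A fold against a group with 0 reads in all libraries is given as a lower bound, computed against a floor of 3 counts over the group. With 1 to 3 reads in a group the ratio of reads is given with its 95% counting interval. Fitted log2 values of such genes depend on the prior count of the fit. They also move by more than 1.5-fold when the library that held those few reads is left out, so the ratio is the value to read.

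There were 28 gene lists fixed before the data were examined, as were the comparisons, the tests, the rule for named genes and most alternatives. The lists held 983 symbols, of which 980 were matched. Lists covered DNA methylation, decitabine uptake and metabolism, cancer-testis genes, interferon response, nucleic acid sensing, antigen presentation on MHC class I and class II, p53 targets, apoptosis, E2F targets, mitosis, DNA repair, MYC targets, T-cell identity, NOTCH1 targets, T-ALL oncogenes, stem and progenitor genes, myeloid, B-cell, NK, erythroid, and epithelial and stromal markers, imprinted genes, cytokines, cholesterol synthesis, the unfolded protein and amino acid stress response, heat shock and mitochondrially encoded genes. Each list was tested in each line with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the 140 tests. Members called were counted over all genes tested and also adjusted over the list alone. Members measured are those that passed the filter. A member with few reads in every DMSO group passes only through a decitabine group with more reads. For lists that are mostly silent in untreated lines, such as the cancer-testis genes, the shares and set tests therefore lean towards rises.

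Genes named for a line were the 10 largest rises and 10 largest falls among protein-coding genes with a symbol that were called, changed at least 2-fold, reached 5 CPM in the higher treatment and had all 3 libraries of one treatment above all 3 of the other. Genes named as shared were the 15 largest rises and 10 largest falls called the same way in each of the 5 lines with 5 CPM, which only 3 and 2 genes met. Named differences between lines were the 5 smallest p with 5 CPM in some group. Any member of a list could be named. Other named genes were chosen after their values were seen, and this is said beside them.

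Alternatives were RLE scaling, no filter on low counts, DESeq2 1.42.0, unstranded counts, the replicate number as a block, each line fitted from its own 6 libraries, an added 2-fold threshold, and leaving out each library or each line in turn. Transcripts restricted to a single line were then measured in the libraries of the other lines, and 3 DMSO libraries held more of them than the other DMSO libraries. Leaving these 3 out, which keeps 27 libraries and 15741 genes, was an alternative chosen after the data were seen. Restricted transcripts were genes with at least 20 CPM in each decitabine library of their line and at most 0.5 CPM in each decitabine library of the others, and, in a looser setting added after the first left only 1 to 4 genes per line, at least 10 and at most 1 CPM. These levels, and those of TLX3 and of TRBC1 in single libraries, are on library sizes without TMM scaling. A non-negative mixture of the 5 lines' mean DMSO profiles was also fitted to each DMSO library. The pipeline was tested on simulated changes: 4-fold changes were recovered for 69.4% to 90.3% of the altered genes per line, and 2-fold changes for 43.1% to 64.6%. Each fold was given to few genes, 58 to 65 of those tested per line. With few changed genes the adjustment is stricter, so these shares may be too low for lines in which many genes were called. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and plots. Genes that share reads with close relatives, such as the MAGE, CTAG, PNMA6, alpha-tubulin, alpha-globin and histone genes, can be counted only from reads that align to a single place, so their levels are uncertain.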

Results

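RNA was measured as read counts per gene in 30 libraries from 5 cell lines of T-cell acute lymphoblastic leukaemia (T-ALL). In each line 3 libraries came from cells given decitabine, a drug that depletes DNA methyltransferases, and 3 from cells given DMSO. The libraries held 2.82 M to 10.6 M gene reads in PEER, 2.49 M to 6.54 M in TALL-1, 2.20 M to 5.26 M in MOLT-16, 10.2 M to 15.4 M in Loucy and 9.93 M to 15 M in PER-117. Unmapped reads made up 2.81% to 12.3% of a library and mitochondrial genes took 3.84% to 6.46% of the gene reads. No pair of libraries within a group was a duplicate, and pairs across groups were not compared. The comparisons asked which genes change when the drug is given, and whether the lines change alike.

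In 3 DMSO libraries, transcripts restricted to another line were found at higher levels than in the other DMSO libraries. TALL-1 DMSO replicate 3 held genes restricted to PEER at 14% of their level in PEER, with all 16 such genes detected (interquartile range 11.6% to 20.2%). MOLT-16 DMSO replicate 3 held the same genes at 20.8% (16.7% to 26.7%). PEER DMSO replicate 2 held genes restricted to MOLT-16 at 7.31%, with 10 of 11 genes detected. Summed over the other lines the 3 libraries reached 10.2% to 23.9%, against at most 1.31% in the other 12 DMSO libraries. All these are values of the looser setting for restricted genes. The stricter one, with 1 to 4 genes per line, gave 12.1% to 19.1% for the 3 libraries and at most 3.35% for the other 12 DMSO libraries. Restricted genes were chosen as low in the decitabine libraries of the other lines. Low shares in decitabine libraries were therefore fixed in advance and do not show that those libraries are free of mixing. A mixture fit on whole DMSO profiles gave PEER shares of 15.6% for the TALL-1 library and 23.8% for the MOLT-16 library, against at most 2.24% in the other DMSO libraries of TALL-1, MOLT-16, Loucy and PER-117. Its total share of other lines set MOLT-16 DMSO replicate 3 apart, at 46.3%. It did not clearly set apart the TALL-1 library, at 19.1%, or the PEER library, at 17.4%. MOLT-16 DMSO replicate 1, which is not among the 3, had 19%, mostly as Loucy and PER-117. For that library the MOLT-16 profile came from DMSO replicate 2 alone. For the PEER library the mixture fit gave a MOLT-16 share of 0 and a TALL-1 share of 8.35%, so its source is less certain. Each main count is given below with all 30 libraries and with these 3 left out, a choice made after the data were seen.

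**Figure D1:**
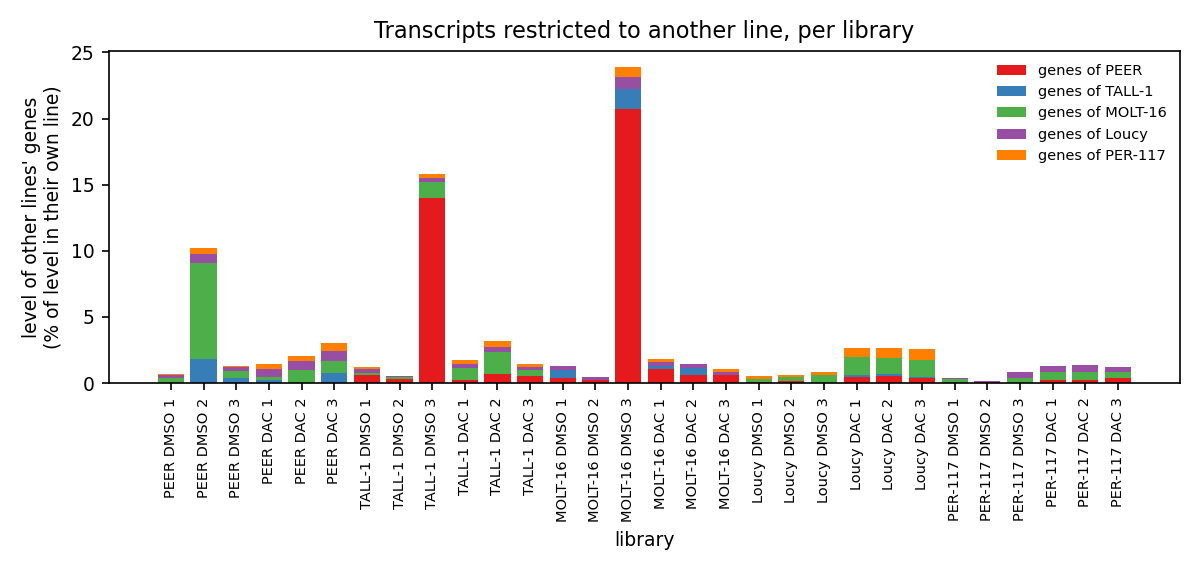
Level of transcripts restricted to another line in each of the 30 libraries, as a percentage of their level in their own line, coloured by that line and stacked. The 3 highest libraries reach 10.2%, 15.8% and 23.9%, and the other 12 DMSO libraries stay at or under 1.31%. The decitabine libraries are low through the choice of the genes.

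The untreated lines differed in the genes that carry out DNA methylation and that take up or metabolise decitabine. All 35 measured members of these lists differed between the DMSO groups, as did 13821 of all 15081 genes. SAMHD1, a hydrolase of deoxynucleoside triphosphates, stood at 50.7 ± 23.9 CPM in MOLT-16 (mean ± SD, n = 3) and at 0.154 to 4.13 CPM in the other lines. SLC29A2, a nucleoside transporter, stood at 0.0195 CPM in Loucy and 0.471 CPM in PER-117, against 18.1 to 26.6 CPM in the others. TET2, an enzyme that oxidises 5-methylcytosine, ranged from 0.106 CPM in Loucy to 24.6 CPM in PER-117. Loucy held the most DNMT3B, a de novo DNA methyltransferase, at 260 ± 26.7 CPM. DNMT1, the maintenance methyltransferase, ranged from 289 ± 215 CPM in MOLT-16, or 173 CPM without DMSO replicate 3, to 877 ± 163 CPM in TALL-1.

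In PEER 12 of 27 cancer-testis and germline genes, 4 of 21 myeloid genes and 4 of 24 cytokines rose with decitabine, and each list passed by camera, with adjusted p under 0.05 at both the preset and the estimated correlation. CTCFL, a testis-specific relative of the insulator protein CTCF, had 0 reads with DMSO and 5.69 ± 1.13 CPM with decitabine (n = 3), at least 31.2-fold higher (chromosome 20, 57495966 to 57525652). PNMA5, a paraneoplastic antigen family gene, rose from 2.35 ± 2.29 to 359 ± 126 CPM (log2 7.33, SE 0.96), a value of 6.67 without DMSO replicate 1 and 8.34 without DMSO replicate 2. MB, which encodes myoglobin, rose from 0.243 ± 0.296 to 20.5 ± 5.78 CPM (log2 6.35, SE 0.55, or 7.65 without DMSO replicate 2). CEBPA, a transcription factor of myeloid differentiation, rose from 1.5 ± 1.35 to 23.4 ± 3.88 CPM (log2 3.97, SE 0.49, or 4.98 without DMSO replicate 2). CD34, a surface marker of blood progenitors, rose from 4.14 ± 2.25 to 29.7 ± 15.2 CPM (log2 2.82, SE 0.47). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 534 genes were higher and 145 lower, of which 442 and 33 changed at least 2-fold.

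Of 27 measured cancer-testis and germline genes, 12 rose and 0 fell in PEER (16 rose adjusted over the list alone; camera adjusted p = 8.14e-17, and 0.00132 with an estimated correlation). Members with few reads in every group are not among the 27, so this share leans towards rises, as do those of the other lines. TKTL1, a transketolase-like gene, rose from 3.83 ± 2.01 to 29.7 ± 6.89 CPM (log2 2.92, SE 0.42). CTAG2, a cancer-testis antigen, had 2 reads with DMSO and 146 with decitabine, a ratio of 66.5 (95% counting interval 18.1 to 555). Of 21 myeloid genes 4 rose (8 adjusted over the list alone; adjusted p = 2.61e-07, and 0.00344 with an estimated correlation). Among them, S100A9, a calcium-binding protein of granulocytes, went from 0 reads to 3.18 ± 1.44 CPM, at least 17.4-fold higher. MPO, which encodes myeloperoxidase, had a ratio of 44.2 (11.9 to 370.3). Of 24 cytokines and chemokines 4 rose (5 adjusted over the list alone; adjusted p = 1.26e-06, and 0.0217 with an estimated correlation), among them CD70, a ligand of the TNF family, with a log2 change of 2.26 (SE 0.44). The other rises named by the rule were PNMA6E with a ratio of 211 (37.4 to 8353), S100A16 with 131 (23.2 to 5220.5), HDC with 46.5 (12.5 to 389), and GPRC5C and BCL6B with log2 values of 4.89 and 4.60. HDC had a log2 change of 5.74, or 6.38 without DAC replicate 1 and 4.61 without DAC replicate 3. BCL6B reached 3.95 without DMSO replicate 1 and 5.97 without DMSO replicate 3. CDKN1A, a cell-cycle inhibitor and p53 target, rose by 1.98 (SE 0.41), or 2.90 without DMSO replicate 2.

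Falls in PEER were smaller. MYC, a growth-promoting transcription factor, fell from 35.9 ± 11.5 to 17.2 ± 2.93 CPM (log2 -1.10, SE 0.30). FABP5, a fatty acid binding protein, fell from 67.5 ± 50.6 to 26.5 ± 5.49 CPM (log2 -1.38, SE 0.38). LGMN, POLI, SDHAF3, NANP, CTNNAL1, MANEAL, MCM9 and ANKH had log2 changes between -1.33 and -1.03. Each of these 10 calls was lost without DMSO replicate 2, at -0.99 to -0.58, and without DAC replicate 1, at -1.34 to -0.84. With the 3 mixed libraries left out FABP5 stood at -0.56 and MYC at -0.79, while MANEAL at -0.84 and ANKH at -0.78 kept their calls. TRAC, the constant region of the T-cell receptor alpha chain, was called lower at -2.38 (SE 0.66), but its value was 0.31 without DMSO replicate 2, which held most of its reads. Genes of mitosis gave 2 falls of 50 (10 adjusted over the list alone) with adjusted p = 1.81e-09, and adjusted p = 0.272 with an estimated correlation. MYC targets gave 2 falls of 43 (6 adjusted over the list alone) with adjusted p = 3.74e-06, and adjusted p = 0.327 with an estimated correlation. The count of higher genes was 344 without DMSO replicate 1 and 335 without DAC replicate 2. The count of lower genes was 68, 54, 34 and 55 without DMSO replicate 2 and DAC replicates 1, 2 and 3. The counts were 740 higher and 141 lower without the 3 mixed libraries.

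In TALL-1 45 of 50 E2F targets and replication genes and 14 of 36 DNA repair genes fell, and both lists passed by camera, with adjusted p under 0.05 at both the preset and the estimated correlation. MCM6, a subunit of the replicative helicase, fell from 200.4 ± 15.3 to 59.0 ± 9.60 CPM (log2 -1.76, SE 0.21, n = 3; chromosome 2, 135839626 to 135876426). PCNA, the sliding clamp of DNA polymerase, fell from 845 ± 27.1 to 297 ± 43.3 CPM (log2 -1.51, SE 0.24), and E2F1, a transcription factor of S-phase genes, from 144 ± 42.0 to 43.2 ± 7.03 CPM (log2 -1.72, SE 0.16). HIST1H4B, a replication-dependent histone gene, rose from 0.911 ± 0.424 to 26.0 ± 4.39 CPM (log2 4.81, SE 0.49). CDC20, an activator of the anaphase-promoting complex, rose from 60 ± 17.1 to 187 ± 24.2 CPM (log2 1.64, SE 0.17). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1017 genes were higher and 923 lower, of which 536 and 288 changed at least 2-fold.

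Of 50 E2F targets and replication genes, 45 fell and 0 rose in TALL-1 (47 fell adjusted over the list alone; adjusted p = 1.09e-58, and 0.00147 with an estimated correlation). TYMS, which makes thymidylate, fell by 1.21 (SE 0.16). Of 36 DNA repair genes 14 fell (18 adjusted over the list alone; adjusted p = 5.47e-10, and 0.00726 with an estimated correlation), among them MSH6, of mismatch repair, which fell by 1.14 (SE 0.16). Genes of mitosis moved the other way, with 24 of 50 higher and 0 lower (31 adjusted over the list alone; adjusted p = 1.54e-17). That call gave adjusted p = 0.0986 with an estimated correlation. PLK1, a mitotic kinase, rose by 1.45 (SE 0.21) and CCNB1, cyclin B1, by 1.24 (SE 0.18). Among the methylation genes DNMT1 fell from 877 ± 163 to 335 ± 62.9 CPM (log2 -1.39, SE 0.31), UHRF1, which recruits DNMT1, fell by 1.31 (SE 0.29), and DNMT3B rose by 0.85 (SE 0.20), although the list as a whole, with 2 rises and 5 falls of 20, had adjusted p = 0.079 (0.0204 without the 3 mixed libraries, and there adjusted p = 0.181 with an estimated correlation). DUT, a dUTP hydrolase, fell by 1.42 (SE 0.23) in the list of decitabine metabolism, where 4 of 15 fell (5 adjusted over the list alone; adjusted p = 0.000104, and adjusted p = 0.132 with an estimated correlation).

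GZMA, which encodes the protease granzyme A, rose in TALL-1 from 0.556 ± 0.296 to 14.2 ± 1.19 CPM (log2 4.62, SE 0.57) and NKG7, a cytotoxic granule protein, from 9.21 ± 2.25 to 33.3 ± 3.60 CPM (log2 1.87, SE 0.22). The NK and cytotoxic list had 3 of 19 higher and 1 lower (the same adjusted over the list alone; adjusted p = 0.0112, and adjusted p = 0.299 with an estimated correlation). GATA3, a T-cell transcription factor, rose by 0.83 (SE 0.16). Among the other rises named by the rule were DIP2C at log2 4.54, DEPP1 with a ratio of 55.6 (18.7 to 272), ENTPD2 with 84.9 (14.8 to 3396), HIST1H2BI with 70.3 (12.2 to 2816) and HIST1H2AH with 39.9 (13.3 to 196). SLC1A7 at 4.60 and CGREF1 at 4.51 moved to 5.42 and 8.70 without DMSO replicate 3. Falls were led, among those kept with each library left out, by CHRNA3 at -1.91, MTHFD2, an enzyme of mitochondrial folate metabolism, at -1.90, BAHCC1 at -1.87, CORO1A at -1.82 and ADGRG1 at -1.81. Calls of KIR3DL2, RSAD2 and CHAC1 (log2 -3.51, -3.07 and -1.92) were lost without DMSO replicate 1, DMSO replicate 3 and DAC replicate 1 in turn, at -3.02, -2.26 and -1.82. ERG, an ETS-family transcription factor, had -4.13, but -1.97 and no call without DMSO replicate 3. HHEX at -3.34 and TRDC at -4.12 stood at 0.75 and -1.50 without that library. The count of lower genes was 611 without DAC replicate 1 and 493 without DAC replicate 3, and without the 3 mixed libraries the counts were 1174 higher and 1022 lower. There 861 of the 1017 higher and 722 of the 923 lower genes were still called.

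In MOLT-16 13 of 27 cancer-testis genes and 13 of 39 p53 targets rose, and both lists passed by camera, with adjusted p under 0.05 at both the preset and the estimated correlation. CTAG2 had 0 reads with DMSO and 9.35 ± 6.22 CPM with decitabine (n = 3), at least 37.3-fold higher (chromosome X, 154651972 to 154653579). TKTL1 rose from 0.255 ± 0.0423 to 25.6 ± 9.48 CPM, a ratio of reads of 110 (95% counting interval 37.1 to 535; log2 6.60, SE 0.70). CDKN1A rose from 1.35 ± 0.681 to 29.3 ± 10.4 CPM (log2 4.37, SE 0.50), and BTG2, an antiproliferative p53 target, from 16.7 ± 3.41 to 50.4 ± 1.85 CPM (log2 1.60, SE 0.22). ZNF48, a zinc finger gene, fell from 42.9 ± 7.48 to 15.3 ± 0.614 CPM (log2 -1.48, SE 0.18). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 331 genes were higher and 152 lower, of which 244 and 37 changed at least 2-fold.

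Of 39 p53 targets, 13 rose and 0 fell in MOLT-16 (19 rose and 1 fell adjusted over the list alone; adjusted p = 1.09e-17, and 0.000233 with an estimated correlation). They included SESN1, a stress-induced sestrin, at 1.44 (SE 0.20) and MDM2, the ubiquitin ligase that restrains p53, at 0.95 (SE 0.15). Of 27 cancer-testis genes 13 rose (16 higher and 1 lower adjusted over the list alone; adjusted p = 3.62e-17, and 0.00177 with an estimated correlation). CEBPA rose by 2.65 (SE 0.40) and CDKN1C, an imprinted cell-cycle inhibitor, by 2.93 (SE 0.39). Of the 22 imprinted genes 3 rose (4 adjusted over the list alone; adjusted p = 0.00502, and adjusted p = 0.205 with an estimated correlation). NOTCH1 rose by 1.28 (SE 0.25), in a list of NOTCH1 targets where 2 of 22 rose and the set test gave adjusted p = 0.485 (0.0162 without the 3 mixed libraries, and there adjusted p = 0.113 with an estimated correlation). CRYM and KRT17, a keratin, had 0 reads with DMSO and were at least 22.9-fold and 21.3-fold higher. PNMA6E had a ratio of 308 (54.7 to 12203), MAEL, of the germline piRNA pathway, 226 (40.1 to 8981), TUBA3D 89.8 (30.3 to 439), NECTIN4 79.1 (13.7 to 3172), SOWAHD 79.1 (13.7 to 3172) and TGM2 84.0 (14.6 to 3368). PTPRD, a receptor phosphatase, and ARID5A had log2 changes of -1.73 and -1.19.

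The counts in MOLT-16 moved more with single libraries than in the other lines. BCL6 at -1.45, ZNF579 at -1.22, DDIT4 at -1.21, HIST1H4J at -1.53 and ECE1 at -1.13 lost their calls without DAC replicate 3, at -1.50 to -1.04. Without DAC replicate 1 the fitted log2 values of CTAG2 and CRYM moved from 9.33 and 8.66 to 8.55 and 7.40. ERG at -4.39 and MAD1L1 at -2.46 stood at -1.01 and -0.88 without DMSO replicate 3, and DNTT, the T-cell terminal transferase, at -0.03 in place of -3.11. The count of higher genes was 199, 220, 1139 and 150 without DMSO replicates 1, 2 and 3 and DAC replicate 1, and the count of lower genes was 850, 29 and 37 without DMSO replicate 3, DAC replicate 1 and DAC replicate 3. Without the 3 mixed libraries 1539 genes were higher and 1249 lower, and 326 of the 331 and 139 of the 152 genes were still called.

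In Loucy, a line with an early T-cell precursor profile, 13 of 24 cytokines, 12 of 19 NK and cytotoxic genes, 11 of 21 myeloid genes and 11 of 27 cancer-testis genes rose, and each list passed by camera, with adjusted p under 0.05 at both the preset and the estimated correlation. GPER1, a membrane oestrogen receptor, had 0 reads with DMSO and 26.1 ± 6.86 CPM with decitabine (n = 3), at least 408-fold higher (chromosome 7, 1082208 to 1093815). GZMA rose from 5.23 ± 0.804 to 46.5 ± 6 CPM (log2 3.15, SE 0.32), MPO from 0.981 ± 0.0632 to 16.0 ± 2.02 CPM (log2 4.01, SE 0.45) and TNF, an inflammatory cytokine, from 0.315 ± 0.231 to 5.00 ± 0.518 CPM (log2 3.91, SE 0.64). BCL2, an inhibitor of apoptosis, fell from 170.4 ± 8.41 to 66.1 ± 6.01 CPM (log2 -1.37, SE 0.13; chromosome 18, 63123346 to 63320128). HIST1H1D, a linker histone gene, fell from 16.6 ± 2.68 to 3.13 ± 1.80 CPM (log2 -2.38, SE 0.33). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1595 genes were higher and 623 lower, of which 1262 and 48 changed at least 2-fold.

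Of 24 cytokines and chemokines 13 rose and 0 fell in Loucy (16 adjusted over the list alone; adjusted p = 4.98e-10, and 0.00344 with an estimated correlation), among them CCL5, a T-cell and NK chemokine, by 4.52 (SE 0.69) and LTB, lymphotoxin beta, by 1.71 (SE 0.21). Of 19 NK and cytotoxic genes 12 rose (12 adjusted over the list alone; adjusted p = 1.94e-07, and 0.0305 with an estimated correlation). Of 21 myeloid genes 11 rose (13 adjusted over the list alone; adjusted p = 7.29e-07, and 0.00726 with an estimated correlation), among them CD33, a myeloid surface receptor, by 1.61 (SE 0.28), and CEBPA, which had 0 reads with DMSO and was at least 16.2-fold higher. Of 27 cancer-testis genes 11 rose (14 adjusted over the list alone; adjusted p = 9.33e-08, and 0.0276 with an estimated correlation), among them SOHLH2, a germ-cell transcription factor, by 3.09 (SE 0.33). Of 58 interferon-stimulated genes 17 rose and 1 fell (20 and 2 adjusted over the list alone; adjusted p = 0.000172). That call gave adjusted p = 0.0979 with an estimated correlation. Of 17 stem and progenitor genes 8 rose (9 higher and 1 lower adjusted over the list alone; adjusted p = 0.000155, and adjusted p = 0.178 with an estimated correlation). TAL1, a T-ALL oncogene, had 1 read with DMSO and 146 with decitabine.

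Falls in Loucy covered 15 of 50 genes of mitosis (20 adjusted over the list alone; adjusted p = 6.71e-10, and adjusted p = 0.257 with an estimated correlation) and 12 of 43 MYC targets (17 adjusted over the list alone; adjusted p = 9.33e-08, and adjusted p = 0.255 with an estimated correlation). CENPF, a kinetochore protein, fell by 0.91 (SE 0.18), GATA3 fell by 1.09 (SE 0.16), MYB, a transcription factor of blood progenitors, fell by 0.94 (SE 0.12) and DNMT3B fell by 1.06 (SE 0.18). The largest falls named by the rule also held HIST1H1B, HIST1H1E, HIST2H2AC and HIST1H4C at -2.35 to -1.57, and RAC3, ITGA4, NRROS and DPF3 at -1.45 to -1.32. The other named rises were SDC4, at least 99.2-fold, PRSS35 with a ratio of 663 (118 to 26211), TRH with 482 (133 to 3985), LRRN3 with 315 (56.1 to 12491), ELN with 200.5 (55.1 to 1662), KCNK17 with 188 (51.6 to 1555), GLI2 with 124 (34.0 to 1033), and CYB561 and RAB17 at log2 7.51 and 7, or 8.51 and 7.77 without DMSO replicate 2. The count of lower genes was 399, 287 and 315 without DMSO replicate 3, DAC replicate 1 and DAC replicate 3. Without the 3 mixed libraries, none of which is from Loucy, 2282 genes were higher and 1259 lower, with a common dispersion of 0.0173 in place of 0.0280.

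In PER-117 19 of 27 cancer-testis genes, 27 of 39 p53 targets and 7 of 11 erythroid and megakaryocyte genes rose, and each list passed by camera, with adjusted p under 0.05 at both the preset and the estimated correlation. MAGEA4, a cancer-testis antigen, had 0 reads with DMSO and 10.7 ± 0.989 CPM with decitabine (n = 3), at least 99.6-fold higher (chromosome X, 151912509 to 151925170). PNMA5 rose from 0.184 ± 0.170 to 232 ± 79.0 CPM (log2 10.21, SE 1.21, or 10.89 without DMSO replicate 1). CDKN1A rose from 13.2 ± 1.67 to 61.6 ± 6.62 CPM (log2 2.23, SE 0.32). MT-ND6, the respiratory gene encoded on the light strand of mitochondrial DNA, fell from 699.7 ± 69.4 to 154 ± 14.1 CPM (log2 -2.18, SE 0.27). CD3D, a chain of the T-cell receptor complex, fell from 167 ± 7.35 to 86.7 ± 4.17 CPM (log2 -0.94, SE 0.15). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1308 genes were higher and 477 lower, of which 1003 and 48 changed at least 2-fold.

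Of 39 p53 targets, 27 rose and 0 fell in PER-117 (30 adjusted over the list alone; adjusted p = 3.96e-19, and 0.000212 with an estimated correlation). FDXR, a mitochondrial reductase, rose by 1.71 (SE 0.20), BBC3, the pro-apoptotic protein PUMA, by 1.54 (SE 0.36) and MDM2 by 0.94 (SE 0.14). Of 27 cancer-testis genes 19 rose (19 higher and 1 lower adjusted over the list alone; adjusted p = 1.88e-22, and 0.000342 with an estimated correlation). Of 11 erythroid and megakaryocyte genes 7 rose and 1 fell (the same adjusted over the list alone; adjusted p = 6.88e-07, and 0.00177 with an estimated correlation). HBA2, an alpha-globin gene, was at least 52.0-fold higher than 0 reads and GATA1, the erythroid transcription factor, rose by 1.49 (SE 0.32). Of 43 MYC targets and ribosome biogenesis genes 16 fell (30 adjusted over the list alone; adjusted p = 8.63e-15), among them NOP16 by 0.82 (SE 0.19). That call gave adjusted p = 0.0947 with an estimated correlation. Of 54 T-cell identity genes 10 fell and 1 rose (the same adjusted over the list alone; adjusted p = 0.0113, and adjusted p = 0.346 with an estimated correlation), among them CD3G at -0.97 (SE 0.16). Of 27 genes in the list of cholesterol and isoprenoid synthesis 12 fell (14 adjusted over the list alone; adjusted p = 7.22e-08, and adjusted p = 0.19 with an estimated correlation). They included FASN at -0.89 (SE 0.23), a list member that encodes fatty acid synthase and is not an enzyme of cholesterol synthesis.

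Other rises named by the rule in PER-117 were PNMA6E and TUBA3D, at least 282-fold and 124-fold above 0 reads. CTAG2 had a ratio of 436 (77.8 to 17233), TBXA2R 217 (38.7 to 8616), DAZL, a germ-cell RNA-binding protein, 165 (56.3 to 804), PGF 165 (45.3 to 1366) and TNFAIP2 124 (42.2 to 604). Falls after MT-ND6 were MANEAL at -2.02, TRPM2, a cation channel, at -1.68, TNFRSF8, which encodes CD30, at -1.66, RGL4 and SERINC2 at -1.47, AFF3 at -1.44 and LCT at -1.26. RNF165 at -1.50 and SPNS3 at -1.29 lost their calls without DAC replicate 1, at -1.24 and -1.26. The count of lower genes was 282, 250, 206, 280 and 294 without DMSO replicates 1 and 2 and DAC replicates 1, 2 and 3. Without the 3 mixed libraries, none of which is from PER-117, 1877 genes were higher and 881 lower.

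**Figure D2:**
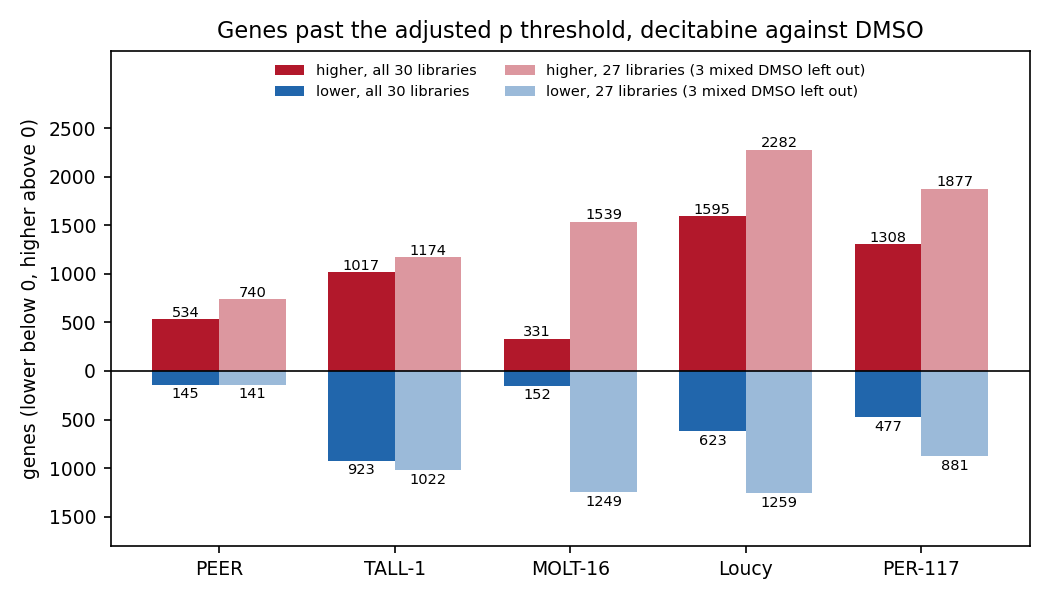
Genes past an adjusted p of 0.05 in each line, higher above 0 and lower below, with all 30 libraries (solid) and with 27 (pale). MOLT-16 moves most, from 331 to 1539 higher and from 152 to 1249 lower.

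Few genes were called the same way in every line. A gene that changes alike in all lines can miss the call in some of them. In simulated data with few altered genes, 2-fold changes were recovered for 43.1% (MOLT-16) to 64.6% (Loucy) of them per line. The shares may be higher in lines where many genes change. PAGE5, a cancer-testis gene of chromosome X (55220355 to 55224108), rose in all 5 lines, from 0.318 ± 0.551 to 7.44 ± 2.41 CPM in PEER, from 0.239 ± 0.413 to 11.5 ± 5.36 CPM in TALL-1, from 0.241 ± 0.219 to 9 ± 2.4 CPM in MOLT-16, from 0.430 ± 0.103 to 17 ± 3.23 CPM in Loucy and from 7.53 ± 0.883 to 44.8 ± 8.91 CPM in PER-117 (n = 3 each). Its DMSO reads in PEER and TALL-1 came from the mixed libraries alone. NXT2, a factor of RNA export, rose by log2 values of 0.62 to 1.77, and PIM2, a pro-survival kinase, by 0.72 to 1.24. In Loucy PIM2 lost its call without DMSO replicate 3, at 0.47, and without DAC replicate 1, at 0.57. PTP4A2, a phosphatase, had log2 changes of -0.96 to -0.37 and GOT2, the mitochondrial aspartate aminotransferase, of -0.67 to -0.37. Their calls in PEER, MOLT-16 or Loucy were lost when any of several libraries was left out, such as DAC replicate 3 of Loucy, where PTP4A2 stood at -0.32 and GOT2 at -0.31.

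By edgeR's quasi-likelihood test in each line, 10 genes were higher in all 5 lines and 2 were lower. If calls were independent between lines, 0.00725 and 0.000117 would be expected. The 5 comparisons share a fit, a filter and a dispersion per gene, so calls are not independent even without a shared response. The excess is therefore no measure of a shared response, and the same holds for pairs of lines below. With RLE scaling, without the filter or with the replicate block, 0 genes were lower in all 5 lines. The other 7 of the 10 were under 5 CPM in some line, among them HBEGF, NKAPL, GPER1, RASSF4, MCEMP1 and RENBP, with mean log2 changes of 2.19 to 6. These were named after their values were seen. Of the 15081 genes 3368 were higher in at least 1 line, 323 in at least 3 and 85 in at least 4, or 5258, 551 and 178 of 15741 without the 3 mixed libraries. Loucy and PER-117 shared 464 higher genes, against 138 expected from their counts, and TALL-1 and MOLT-16 shared 50, against 22.3. With the 3 mixed libraries left out these were 751 against 272 and 148 against 115, so that the excess shared by TALL-1 and MOLT-16 was smaller relative to its expected count. With the lines as replicates, 8 of 13830 genes were higher, 7 of them at least 2-fold: ADAMTS4, ALDH3B1, ADAMTS7, KSR1, AC004490.1, CRYBB1, PIM2 and PAGE5, with log2 changes of 0.99 to 4.91, also named after their values were seen. In that fit edgeR called 0 genes lower, with 1085 lower at an unadjusted p under 0.05, while DESeq2 called 383 higher and 317 lower. With 1 line left out, edgeR called 0 genes higher without PEER, MOLT-16 or Loucy, 2 without PER-117 and 46 without TALL-1. In the absence of the 3 mixed libraries 33 genes were higher and 5 lower in each line, and 66 were higher and 11 lower with lines as replicates.

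**Figure D3:**
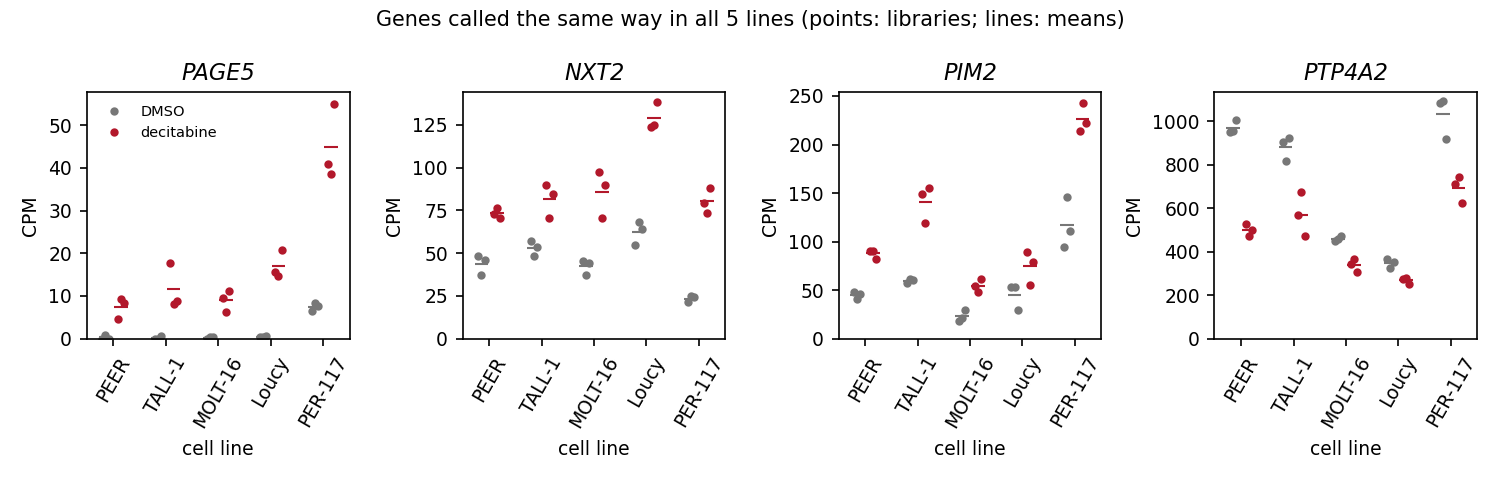
CPM of PAGE5, NXT2, PIM2 and PTP4A2 in each library (points) by line and treatment, with group means (lines). PAGE5 means rise to between 7.44 and 44.8 CPM with decitabine.

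The response differed between lines for 2049 genes, 13.6% of those tested. ARRDC3, an arrestin-domain adaptor of receptor turnover, rose in TALL-1 from 48.9 ± 10.8 to 661 ± 61.3 CPM (log2 3.76, SE 0.20, n = 3) and had log2 values of 0.05 to 0.36 in the other lines (adjusted p of the difference = 1.1e-09). SUSD3 rose by 2.72 (SE 0.25) in Loucy and 3.67 (SE 0.28) in PER-117, where its DMSO level was 0.508 and 0.435 CPM, against -0.31 to 0.35 in lines that held 20.3 to 43.7 CPM untreated. PECAM1, the adhesion molecule CD31, rose in Loucy from 0.212 ± 0.0191 to 9.46 ± 0.730 CPM (log2 5.37, SE 0.37). In PEER its value of 0.98 lost its call without DMSO replicate 3, at 0.70. NFIA, a transcription factor, had 1 read in Loucy with DMSO and rose to 4.51 ± 0.723 CPM, the line where it was lowest. WFS1, an endoplasmic reticulum protein, rose by 6.37 in PER-117 (8.08 without DMSO replicate 1), 3.67 in Loucy and 2.00 in MOLT-16, and had 0.07 in TALL-1. Its rise of 1.01 in PEER lost its call without DMSO replicate 2, at 0.75, and also without DMSO replicate 3, DAC replicate 1 or DAC replicate 3, at 1.04, 1.04 and 0.92. The difference also passed for DNMT1, with log2 changes of -0.53, -1.39, 0.70, -0.31 and -0.34 in PEER, TALL-1, MOLT-16, Loucy and PER-117 (adjusted p = 0.02), and for DNMT3B. The values of DNMT1 were -0.26, -1.52, 1.41, -0.32 and -0.34 without the 3 mixed libraries, and its rise in MOLT-16, not called with all 30, had adjusted p = 7.45e-05. Of 5053 genes called in any line, 157 were higher in one line and lower in another, or 632 of 8010 without the 3 mixed libraries. The difference was called for 4373 genes without the 3 mixed libraries and for 3807 without MOLT-16 DMSO replicate 3 alone.

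Over all lists and lines, 54 of 140 set tests passed at the preset correlation and 14 with the estimated one. The 14 were cancer-testis genes in PEER, MOLT-16, Loucy and PER-117, p53 targets in MOLT-16 and PER-117, E2F targets and DNA repair in TALL-1, myeloid genes in PEER and Loucy, cytokines in PEER and Loucy, NK genes in Loucy and erythroid genes in PER-117. With the 3 mixed libraries left out, 63 tests passed at the preset correlation and 25 with the estimated one. The 25 were these 14 and 11 others: stem and progenitor genes in PEER and Loucy (adjusted p = 0.0105 and 0.00962 with the estimated correlation), epithelial and stromal genes in PEER and Loucy (0.00501 and 0.00809), B-cell genes and NK genes in PEER (0.0145 and 0.0396), cytokines and decitabine metabolism in TALL-1 (0.0102 and 0.046), and MYC targets, cholesterol synthesis and imprinted genes in PER-117 (0.0111, 0.0396 and 0.0396). At the preset correlation 11 tests were gained, among them p53 targets in PEER (0.0158), epithelial and stromal genes in TALL-1 (0.0162) and the unfolded protein and amino acid stress list in PEER and TALL-1 (0.00256 and 4.57e-06), and 2 were lost, both in MOLT-16. None of the 11 held with an estimated correlation, where these 4 had adjusted p = 0.192, 0.0533, 0.418 and 0.229. B-cell genes rose in 3 of 19 in PEER, 3 in MOLT-16 and 8 in Loucy, where 2 also fell (4 and 4 higher, and 8 higher and 3 lower, adjusted over the list alone; adjusted p = 0.000342, 0.00609 and 0.000311), with adjusted p = 0.0933, 0.205 and 0.0947 with an estimated correlation. The call in MOLT-16 was 1 of the 2 lost without the 3 mixed libraries (adjusted p = 0.0733). Epithelial and stromal genes rose in 3 of 19 in PEER, 7 in Loucy and 4 in PER-117 (7, 10 and 4 adjusted over the list alone; adjusted p = 0.000442, 0.00184 and 0.0258), with adjusted p = 0.255, 0.299 and 0.485 with an estimated correlation. Mitochondrially encoded genes in MOLT-16 had 2 of 13 higher (6 adjusted over the list alone; adjusted p = 3.77e-05, and adjusted p = 0.142 with an estimated correlation). The unfolded protein and amino acid stress list in MOLT-16 had 2 of 29 lower (6 higher and 13 lower adjusted over the list alone; adjusted p = 0.00571, and adjusted p = 0.488 with an estimated correlation). T-ALL oncogenes passed in MOLT-16 with 1 of 36 higher and 1 lower (the same adjusted over the list alone; adjusted p = 0.0489, and adjusted p = 0.572 with an estimated correlation). That call was lost too without the 3 mixed libraries, at adjusted p = 1, where the median log2 change of the list was -0.01 in place of -0.33.

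Several lists fixed for this drug did not pass with all 30 libraries. Nucleic acid sensing genes had at most 1 of 10 higher and 2 lower in any line, with adjusted p of 0.327 to 0.865. MHC class I genes reached 3 of 16 higher in Loucy (4 adjusted over the list alone; adjusted p = 0.11), where HLA-F, a non-classical class I gene, rose by 1.72 (SE 0.31). MHC class II genes reached 2 of 10 there (2 adjusted over the list alone; adjusted p = 0.147). Apoptosis regulators ranged from 1 of 30 higher in PEER to 5 in PER-117 (6 adjusted over the list alone), with 0 to 2 lower and adjusted p of 0.14 to 0.956. NOTCH1 targets had 1 to 4 of 22 higher and 0 to 2 lower, with adjusted p of 0.292 to 0.985. Heat shock genes had at most 3 of 15 higher, in TALL-1, where 1 was lower (6 and 1 adjusted over the list alone; adjusted p = 0.107), and 2 lower in Loucy (adjusted p = 0.0502). Interferon-stimulated genes outside Loucy had 1 of 58 higher in PEER (0 adjusted over the list alone; adjusted p = 0.978) and in MOLT-16 (1 adjusted over the list alone; adjusted p = 0.711), 6 higher and 8 lower in TALL-1 (8 and 9 adjusted over the list alone; adjusted p = 0.865), and 6 higher in PER-117 (6 higher and 4 lower adjusted over the list alone; adjusted p = 1). Cancer-testis genes in TALL-1 had 3 of 27 higher and 1 lower (the same adjusted over the list alone; adjusted p = 0.0883). Some of these lists passed with the 3 mixed libraries left out: MHC class I genes in Loucy with 7 of 16 higher (adjusted p = 0.0448), NOTCH1 targets in MOLT-16 with 2 of 22 higher and 1 lower (0.0162, median log2 change 1.61), heat shock genes with 5 of 15 higher in TALL-1 (0.0325), 4 higher in MOLT-16 (0.000649) and 2 higher and 6 lower in Loucy (0.0151), and cancer-testis genes in TALL-1 with 5 of the 31 then measured higher and 1 lower (0.0119, median log2 change 1.73). None of these calls held with an estimated correlation, which gave adjusted p of 0.113 to 0.311.

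**Figure D4:**
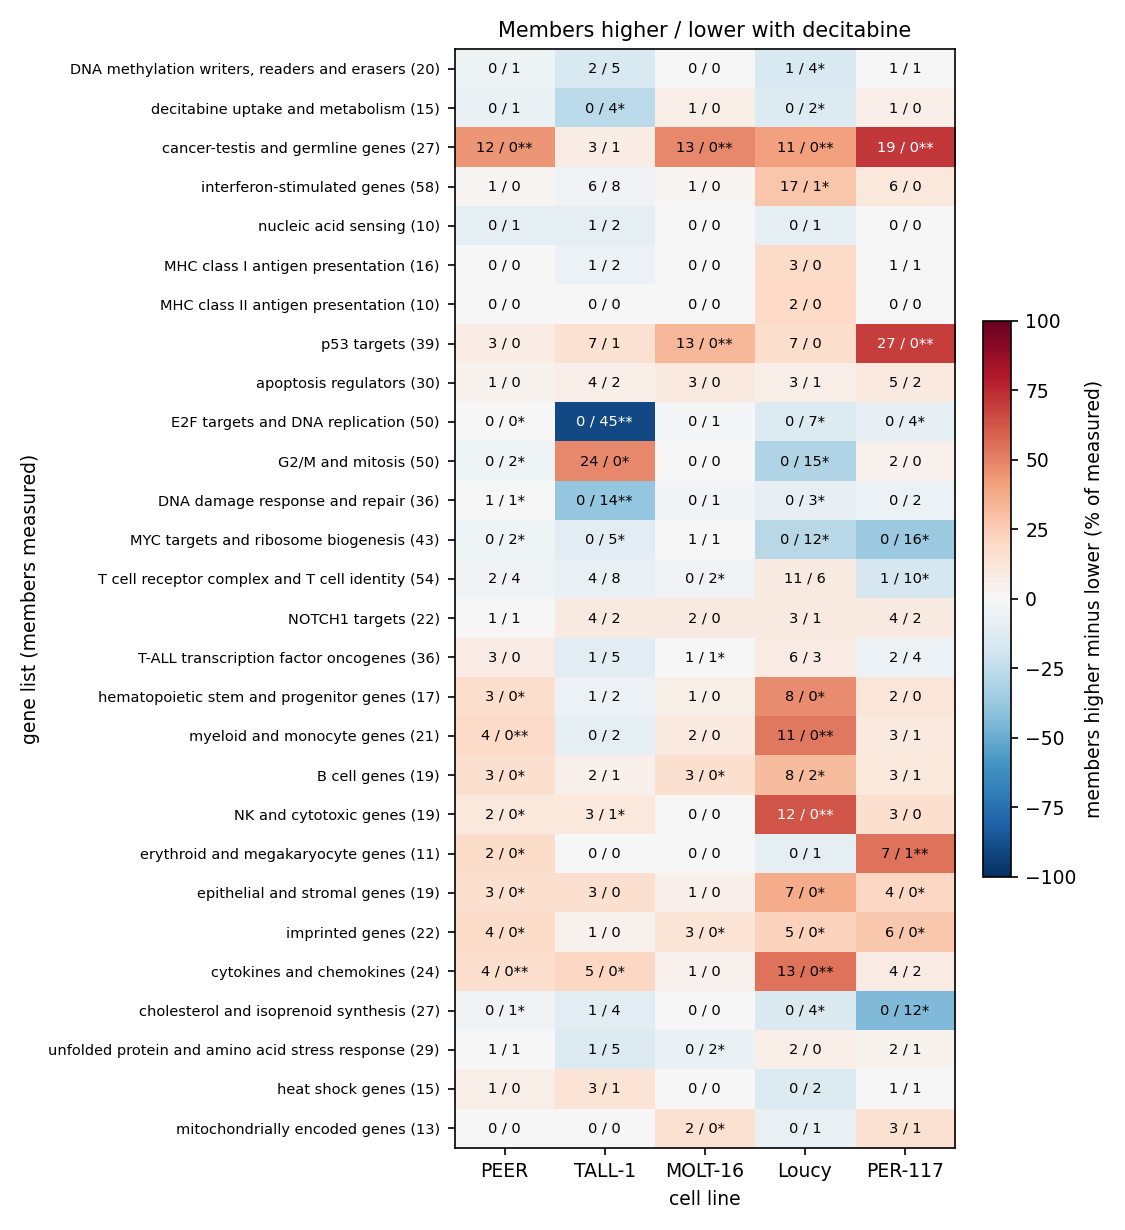
Members of each gene list higher / lower with decitabine, by line, with colour for the difference as a percentage of members measured. One star marks an adjusted p under 0.05 at the preset correlation and a second star marks the 14 tests that also pass with an estimated correlation.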

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

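All tests of explanations in this part were chosen only after the results were seen. The response to decitabine differed between the lines for 2049 genes by the test of the difference itself. Other splits of the libraries within lines gave at most 227 such genes in 39 draws, so that 1 of 40 splits, the real one, gave as many. Those other splits mix treated and untreated libraries, so the response itself widens the spread within their groups and lowers their counts. They cannot exclude chance between cultures either, since the libraries of a group may be technical repeats. With lines as replicates the treatments can be exchanged within lines in 16 splits, too few for a share under 0.05. The real one called 8 genes and the highest other 0. Of 100 splits of the 10 sums that ignore the lines, 4 gave at least 8 genes, the real one included, and the highest gave 11. Within a line 3 libraries against 3 make 10 splits, too few for a share under 0.05. The real split called 679 genes in PEER (highest other 98, 1 of 10 as large), 1940 in TALL-1 (70, 1 of 10), 2218 in Loucy (0, 1 of 10) and 1785 in PER-117 (0, 1 of 10). In MOLT-16 the real split called 483 genes, and the split of DMSO replicates 1 and 2 with DAC replicate 2 against the rest called 975, so 2 of 10 were as large and the 6 libraries hold a structure other than treatment.

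Reads on the strand opposite to the gene were outside the main comparisons. They were tested only for genes without another gene on the opposite strand within 5 kb, 23865 in all. Of these, 97 had enough such reads. With decitabine 2 rose in PEER, 2 in TALL-1, 16 in Loucy and 4 in PER-117 (edgeR, adjusted over the 97 genes). Falls were 1 in Loucy and 1 in PER-117, and none passed in MOLT-16. With the 3 mixed libraries left out 2 rose in PEER, 1 in TALL-1, 2 in MOLT-16, 17 in Loucy and 9 in PER-117, and 1 fell in Loucy and 2 in PER-117. Reads opposite to LINC00861, a long non-coding RNA gene on chromosome 8 (125922308 to 125951249), rose by log2 values of 5.33 in PEER (SE 0.62), 4.22 in TALL-1 (SE 0.48) and 3.01 in PER-117 (SE 0.40). Its own strand had values of 0.20, 0.25 and 1.29 there, none of them called.

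Transcripts of other lines in 3 DMSO libraries were followed up because they bear on every count in PEER, TALL-1 and MOLT-16. By their file names, though not by the titles, all 3 are replicate 3 of the DMSO group of their line, which may reflect a shared preparation that the labels do not give. An even exchange of reads among all 30 libraries is argued against, since genes restricted to Loucy or PER-117 stayed at or under 0.907% of their own level in the 3 libraries in the looser setting and at or under 1.04% in the stricter one. The mixture fit on whole profiles gave larger shares of these lines, 5.20% Loucy and 11% PER-117 in the MOLT-16 library and 4.70% and 4.38% in the PEER library, but also 9.04% and 6.42% in MOLT-16 DMSO replicate 1, which is not among the 3. RNA or reads of PEER may be the source in the TALL-1 and MOLT-16 libraries, as the lower quartile of 16 PEER-restricted genes was 11.6% of the PEER level or more in both. RNA from a sample outside the 5 lines is a further possible source: TLX3, a T-ALL oncogene, had reads in 18 of 18 libraries of PEER, TALL-1 and MOLT-16 (0.237 to 31.6 CPM without TMM scaling) and in 0 of 12 of Loucy and PER-117, and the 27 other genes in excess were higher in 23 cases in PEER DAC replicate 3 than in the rest of its group. That test leaves it open, because PER-117 DAC replicate 2 reached 22 of 27. Among all genes with a group mean of at least 5 CPM, 58.4% were higher in this PEER library and 53.3% in this PER-117 library. Part of both counts may therefore follow the library as a whole. The bound was tightened after a first criterion of 70% had been met and after some of the 35 genes in excess had been looked at informally. The 27 tested were those of the 35 not looked at before. No biological explanation was tested.

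Reads on the strand opposite to the 12 mitochondrial heavy-strand genes fell from 4486 to 1164 CPM in PER-117 (log2 -1.95, SE 0.19) and from 1067 to 571 CPM in Loucy (log2 -0.90, SE 0.19), while the other lines had -0.19 to 0.08. A general loss of mitochondrial RNA is argued against, because the own-strand sum of these genes in PER-117 changed by 0.34 (SE 0.13) the other way. DNA carried over into the libraries could also give opposite-strand reads. Where DNA is read from both strands alike, less of it cannot take more reads from a strand than the other strand of the same gene held. In PER-117 the loss went 1187 CPM beyond this, 35.7% of the 3322 CPM lost over the 12 genes and more than 2 SD (SD 506 CPM), which argues against such DNA as the whole cause there. All of that excess lay in MT-ND5. In Loucy the loss stayed within the bound, so DNA stays open there, and DNA read from one strand more than the other stays open in both lines. MT-ND6 was not among the 12. Its own strand had log2 changes of -2.18 in PER-117 and -1.22 in Loucy (SE 0.27 in both). Its opposite strand rose there by 0.84 and 0.55 (SE 0.13 in both). As values of 1 gene, these do not settle the question for the 12. A lower level of light-strand transcripts, which include MT-ND6, is a candidate explanation that stays open too. It was not tested apart from these values.

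Histone genes rose in TALL-1 while E2F targets fell. Of 44 histone genes measured, 33 rose there, with a median log2 change of 2.59, and 5 rose and 11 fell in Loucy. Transcripts of other lines are argued against, since 33 were also higher without the 3 mixed libraries. A different share of cells in S phase stays open, since the E2F targets are themselves part of the pattern and no other measure of it was tested. Also open is a change in how histone transcripts end, such as more polyadenylated ones that this kit can capture, which may differ between lines and was not tested.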

How the results depend on the processing

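The settings run were those fixed before the data were examined, except leaving out the 3 mixed DMSO libraries, which was chosen after the results were seen. Of 248 named fold changes, 191 kept their call under every alternative other than leaving out 1 library, and 188 kept it whichever single library was left out. Per setting 244 of 248 kept their call with RLE scaling, 243 without the filter, 238 with DESeq2, 238 of 244 with unstranded counts, 234 of 248 with the replicate block, 198 of 238 from a line's own 6 libraries and 233 of 248 without the 3 mixed libraries. The rest lost the call with the same sign, apart from 2 genes. TRAC in PEER, at -2.38, was 0.33 without the 3 libraries and ran from -2.92 to 0.31 with 1 library left out. HHEX in TALL-1, at -3.34, was 0.75 without the 3 and ran from -3.87 to 0.75 with 1 left out. In both the sign followed the 1 DMSO library that held most of the reads. Small changes may be missed: in simulated data 1.5-fold changes were recovered for 6.25% to 26.6% of the few altered genes. The share may be higher in lines where many genes change.

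Of the counts of genes, those not mentioned here stayed within 1.5 times their main value. A count can stay while its genes change: of the 145 lower genes in PEER, 58 were still called without the 3 mixed libraries. The cause was not tested for any that moved, except where fewer libraries or an added threshold give it by construction. Without the 3 mixed libraries the counts of Loucy and PER-117 moved with their own libraries unchanged. They can have moved only through what the fit shares between lines, such as the filter, the scaling and the dispersion. The common dispersion was then 0.0173 in place of 0.0280. RLE scaling gave 89 lower genes in PEER and 0 genes lower in each of the 5 lines. Without the filter there were 247 lower in PEER, 652 higher and 374 lower in MOLT-16, 1232 higher and 449 lower with lines as replicates, 0 lower in each line and 3129 with a response that differed between lines. DESeq2 gave 514 higher and 283 lower in MOLT-16, 383 higher and 317 lower with lines as replicates, 19 higher in each line and 3281 differing. Unstranded counts gave 5 higher with lines as replicates. With the replicate number as a block 0 genes were lower in each line, and 12 of 13 counts stayed within 1.5 times. Whether the numbers pair the samples stays open: in PER-117 the decitabine and DMSO libraries of the same number were the most alike (correlation 0.0744 to 0.196, against at most 0.0501 for other pairs), while in each of the other lines the most alike pair had different numbers by title. By the numbers of the file names the most alike pair of PEER, at 0.266, has the same number, and its other same-number pairs had 0.223 and 0.00432. The pair at 0.266 is DMSO replicate 2 by title, a mixed library, and DAC replicate 3. These had the most TLX3 in PEER, at 31.6 and 15.2 CPM without TMM scaling. Their likeness may come from such transcripts and cannot be told apart from pairing. A change of at least 2-fold as well left 33 lower in PEER, 536 higher and 288 lower in TALL-1, 37 lower in MOLT-16, 48 lower in Loucy, 48 lower in PER-117 and 0 lower in each line. Fits of a line's own 6 libraries gave 276 higher and 30 lower in PEER, 58 higher and 1 lower in MOLT-16, 1344 lower in Loucy and 1390 lower in PER-117. An estimated correlation between genes left 14 of 54 list calls, and 25 of 63 without the 3 mixed libraries.

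Without the 3 mixed libraries there were 1539 higher and 1249 lower in MOLT-16, 1259 lower in Loucy, 881 lower in PER-117, 66 higher and 11 lower with lines as replicates, 33 higher and 5 lower in each line, and 4373 differing between lines. Leaving out 1 library at a time gave 335 to 495 higher and 34 to 132 lower in PEER, 493 to 822 lower in TALL-1, 150 to 1139 higher and 29 to 850 lower in MOLT-16, 287 to 495 lower in Loucy, 206 to 331 lower in PER-117 and 1588 to 3807 differing between lines. Leaving out 1 line at a time gave 0 to 46 higher and 0 to 1 lower with lines as replicates, the highest in both without TALL-1.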

Other observations

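The test of chromosome X in this part was written before its result was seen, and the histone, DNA methyltransferase and TRBC1 values were chosen afterwards. CDKN1C, an imprinted inhibitor of the cell cycle on chromosome 11, rose in PEER by 3.16 (SE 0.63, or 5.87 without DMSO replicate 2), in MOLT-16 by 2.93 (SE 0.39), in Loucy by 4.92 (SE 0.47) and in PER-117 by 3.33 (SE 0.39). Imprinted genes as a list had 4 of 22 higher in PEER, 5 in Loucy and 6 in PER-117 (4, 5 and 8 adjusted over the list alone), with adjusted p = 0.00814, 0.00502 and 0.00053, and adjusted p = 0.23, 0.205 and 0.109 with an estimated correlation. BCL2 fell by 0.98 (SE 0.15) in PER-117, the other line in which it was called lower beside Loucy. LTB rose in Loucy and fell by 0.91 (SE 0.20) in PER-117. RRM2B, a p53-induced subunit of ribonucleotide reductase, rose by 1.01 (SE 0.18) in PER-117.

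In TALL-1 the unfolded protein and amino acid stress list had 1 of 29 higher and 5 lower (the same adjusted over the list alone; adjusted p = 0.0642), among them SHMT2 at -1.43 (SE 0.31) and PHGDH at -1.27 (SE 0.32). There 1 was higher and 10 lower without the 3 mixed libraries (adjusted p = 4.57e-06, and adjusted p = 0.229 with an estimated correlation). Histone genes differed in their response between lines for 36 of 44. In Loucy methylation genes had 1 of 20 higher and 4 lower (1 and 5 adjusted over the list alone; adjusted p = 0.00515, and adjusted p = 0.165 with an estimated correlation).

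TRBC1, a constant region of the T-cell receptor beta chain, varied widely within the groups of PEER and TALL-1. In TALL-1 it was called lower at -2.36 (SE 0.76), a call that was lost when any library other than DMSO replicate 2 was left out, at -2.65 to -1.94. On library sizes without TMM scaling it stood at 160, 15.4 and 186 CPM in the TALL-1 DMSO libraries, at 225 CPM in PEER DMSO replicate 2, and at 128 CPM in PEER DAC replicate 3 against 9.50 to 10.1 CPM in the other decitabine libraries of PEER. The 3 libraries left out above are therefore not the only ones that stand apart.

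Genes risen with decitabine lay on chromosome X more often than on the autosomes in MOLT-16, with an odds ratio of 1.85, though its p by Fisher's exact test did not pass adjustment (adjusted p = 0.336). The cancer-testis list may account for this excess. Without that list the odds ratio was 1.41 (95% interval 0.754 to 2.42, adjusted p = 0.444 by Fisher's exact test), the highest of the 5 lines, and its interval is too wide to decide. With the 3 mixed libraries left out the odds ratio in MOLT-16 was 1.15 (unadjusted p = 0.323) with the list and 1.07 (unadjusted p = 0.644) without it, so the excess itself depends on those libraries.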
